A study of Drosophila melanogaster with 3 samples.

How the data were processed

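The series describes 3 Drosophila melanogaster ovary samples from transgenic strains. Global run-on sequencing (GRO-seq, which reads RNA still being transcribed) of strains 1.9 and 3.6 was not analysed here. The small RNA library of strain 2.4 was analysed, so there is 1 library, no replicate and no comparison between groups. Per the labels' protocols, total RNA was isolated with Trizol and RNA of 19 to 29 nt was cut from a polyacrylamide gel before the library was made. The submitters' processing notes name Bowtie and genome build dm3 for this sample, and Bowtie2 and dm3 for GRO-seq, with no version. The analysed list holds no alignment.

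The deposited list gives counts: each line is a distinct sequence with the number of reads that had it, with no normalization. How the authors clipped the 3′ adapter before they deposited the list is not given in the sources used here. The list held 13919233 reads of 5124861 distinct sequences, from 18 to 50 nt long. Of these sequences, 83.3% were read once. The library has no molecular identifiers, so each interval given covers counting error only.

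No reference genome was used here. Of the 11 results fixed before the data were examined, 5 need one and were not computed. These are the percent of reads that match the genome, the percent of those in annotated transposable elements, the percent of uniquely matching reads in the piRNA clusters 42AB and flamenco, and the number of 5 kb windows that hold 90% of such reads. Results on transposons, transgene parts and miRNAs were instead computed by matching reads to published sequences written out from general knowledge. These were 19 proteins, 2 nucleotide stretches of P-element vectors, 2S and 5S rRNA and 54 mature miRNAs. The lists were drawn up after the data had been seen, and they come from no database in use here. The name of each item therefore rests on such a sequence and on 2 checks, the share of its residues that reads covered and the reads that the same protein written backwards matched. Of the transposon proteins, 5 of 6 had at least 90% of residues covered and were pooled. The gene table used for names is of assembly Release 6, which differs from dm3, so no coordinates are given. It held 53 of the 54 miRNA names, all 7 single genes and all 6 Hsp70 copies.

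A read matched a protein when all complete codons of 1 of its 6 reading frames spelled a stretch of at least 7 residues of it. For a read of 21 nt only 1 of 3 frames on each strand has 7 complete codons. Such a match gives the strand and the 5′ end of the read on the coding sequence whatever the codons. It cannot tell apart copies, or related genes, that encode the same run of residues, and the simulated test held no related genes. Vector stretches and rRNA had to match exactly over the whole read. A miRNA read had at most 25 nt and began with the first 20 nt of the listed sequence. miR-2c shares those 20 nt with mir-2a, so the name mir-2a covers both. RPM is reads per 1000000 reads of the whole 23 to 29 nt class, or of 20 to 24 nt for miRNAs.

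Overlaps were counted between the 5′ ends of reads on opposite strands. A pair of positions counts as the lower of its 2 read numbers, and the 10 nt share is the percent of all overlaps from 1 to 23 nt that were 10 nt. The z value sets the number of 10 nt pairs against the mean and SD of the other overlaps and describes this library only. For a measure that needs no names, reads of 20 to 31 nt seen at least 2 times were joined into unitigs (stretches without a fork) from 19-base words. A unitig ended where a second base had over 10% of the coverage of the first, and those of at least 40 nt were kept. The unitig overlap and the strand of w reads were added as results after the data had been seen. Shares have exact Clopper-Pearson 95% intervals and counts exact Poisson intervals. The percentile of a gene among genes of like exon length, fixed before the data were examined, was replaced by a panel of 4 mRNAs measured in the same way.

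Leftover adapter was recognised by 13 bases of its inner part, and an insert was kept from 18 nt. The sequence GTTTAAAC, which is the 8-base recognition site of the restriction enzyme PmeI, was searched for in all reads. The vector and reporter genes were lacI, tetA, bla, lacZ and neo. The matching was tested on simulated data. Of 3000 simulated reads of copia, w and Hsp70, 2999 came back with the right gene, strand and position, none of 3000 random reads matched, and the percent antisense came back as 55.6% against a simulated 55.6%. The 10 nt share came back as 12.1% against 12.1%, and 50 of 50 simulated sequences came back as unitigs. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

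Named by rules fixed before the data were examined were the 10 miRNAs with most 20 to 24 nt reads, a list of ovary miRNAs, a list of miRNAs of other tissues, lists of transposons active in the germ line or in follicle cells, the transgene parts w, y, Hsp70, Act5C, Adh and the P-element, and a gene list that includes vas. Members of these lists for which no sequence was written out were not analysed here, among them the I-element, the telomeric elements and the hairpin siRNA genes. Of the pooled elements, 2 have numbers for names and are given by their lists only, as the further gypsy-group element of the follicle-cell list and the element of the intermediate list. These and gypsy were matched by a pol region alone, and the sequences written out for these 3 are the least certain. The mRNAs alphaTub84B and eEF1alpha1 and the vector genes were chosen after the data had been seen. Alternatives counted each distinct sequence once, left out sequences read once, used 24 to 28 nt instead of 23 to 29 nt, left out listed miRNAs and rRNA, or allowed 1 mismatch in a miRNA. Those that clip or leave out technical reads, and all of those for unitigs and for the strand of w reads, were added after the data had been seen.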

Results

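The study asked how new piRNA clusters form at transgene insertions. PIWI-interacting RNAs (piRNAs) are small RNAs of 23 to 29 nt that silence transposons in the fly ovary. Small RNA from ovaries of strain 2.4 was read in 1 library of 13919233 reads. The 2 GRO-seq samples, from strains 1.9 and 3.6, were not analysed here, so values below describe 1 library and no difference between strains was measured. What the transgene holds is not stated in the labels. Intervals are exact 95% intervals (Clopper-Pearson for shares, Poisson for counts) and cover counting error only, and names rest on sequences written out from general knowledge.

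Small RNAs of piRNA length made up most of the library. Reads of 23 to 29 nt were 69.80% of all reads (9715139 reads, 95% CI 69.77 to 69.82%), with most reads at 26 nt (2026661 reads, 14.6%). The peak depends on reads that hold the 8-base site of the restriction enzyme PmeI, without which 25 nt (1798299 reads) lies above 26 nt (1785554). Reads of 20 to 22 nt, the length of siRNAs and of many miRNAs, were 11.82% (95% CI 11.81 to 11.84%), mostly of 21 nt (1065177 reads). Listed miRNAs also gave 534722 of the 1671569 reads of 23 nt, which are counted in the 23 to 29 nt class. A uridine at the first position (1U), which PIWI-bound piRNAs usually carry, was found in 62.95% of 23 to 29 nt reads (95% CI 62.92 to 62.98%). At positions 2 to 9 of the same reads the mean share of U was 26.2%, and 20 to 22 nt reads outside the listed miRNAs began with U in 35.4%. Without listed miRNAs and rRNA, 60.8% of 23 to 29 nt reads had 1U. An adenine at position 10 (10A) was found in 36.9% of 23 to 29 nt reads that did not begin with U (mean of other positions, 33.7%) and in 24.1% of those that did (28.9%). Reads with the PmeI site or of vector genes were counted in these 10A shares, which were not recomputed without them. Reads of 22 nt numbered 77034, or 5.63% of the mean of 21 and 23 nt, so length shares next to 22 nt are uncertain.

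**Figure D1:**
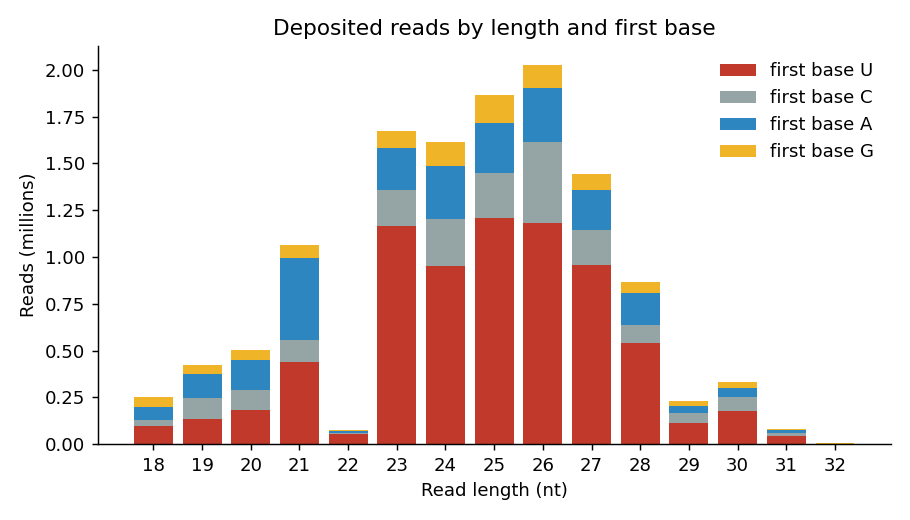
Number of deposited reads (in units of 1000000) by read length from 18 to 32 nt, with bars split by the first base. The highest bar is 26 nt (2026661 reads), or 25 nt without reads that hold the PmeI site, U is the commonest first base from 22 to 32 nt, and the bar at 22 nt (77034 reads) is far below both neighbours.

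bantam was the most read miRNA, and miRNAs of the list of other tissues were low. This growth-promoting miRNA, with the sequence UGAGAUCAUUUUGAAAGCUGAUU, had 329457 reads of 20 to 24 nt, or 66836 reads per 1000000 reads of that length (RPM, 95% CI 66607 to 67064). It was followed by mir-305 with 24452 RPM, a low estimate since exact matching misses reads with a mismatch (15.1% at position 4), then by mir-12 with 14783 and mir-995 with 12115. The other members of the 10 most read were mir-996, mir-318, mir-13b, mir-2a, mir-14 and mir-184, at 5111 to 4211 RPM. These 10 held 74.1% of all reads of the 54 listed miRNAs. Of the 15 miRNAs of the ovary list, 4 were among them, namely bantam, mir-318, mir-14 and mir-184. The ovary list as a whole held 49.6% of listed reads, of which bantam alone held 34.1% and the other 14 members 15.5%. Its median of 1423 RPM was close to the 1333 RPM of the 32 miRNAs on neither list, which held the other 6 of the 10 places. Its lowest member was mir-313 with 75.1 RPM, and mir-989, needed for border cell migration in the ovary, had 3923. Listed miRNA reads of 22 nt were scarce (20954, against 299162 of 21 nt and 534722 of 23 nt). Counts of miRNAs listed at 22 nt, among them mir-318, mir-184, mir-996 and mir-13b, may therefore be too low. The ranks, list shares and medians were not corrected for this.

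The 7 miRNAs of other tissues held 0.837% of listed reads, with a median of 146 RPM. Let-7, which marks adult somatic tissue, was the highest at 985 RPM, and mir-1 of muscle had 243. mir-124 of neurons had 3 reads (0.609 RPM, 95% CI 0.126 to 1.78) and mir-133 of muscle had none (upper bound 0.748 RPM). Listed miRNAs made up 21.7% of 20 to 22 nt reads (95% CI 21.7 to 21.8%), and 0.0802% when each distinct sequence was counted once. Neither reads of miRNAs outside the list nor listed miRNA reads of 23 nt (534722) and 24 nt (74178) are in this share. It was 25.5% with 1 mismatch allowed. Of 21 miRNAs listed at 22 nt with at least 100 reads, 14 had 21 nt and 5 had 23 nt as their commonest length.

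Transposon coding sequences were covered by reads of both strands, mainly antisense. Over the 5 pooled elements, 69924 reads of 23 to 29 nt matched (7197 RPM, 95% CI 7144 to 7251), and 73.4% of these were antisense (95% CI 73.1 to 73.8%). The same proteins written backwards matched 63 reads. Antisense reads began with U in 75.7% and sense reads in 54.4%, while sense reads had 10A in 46.6% against 34.8% A at other positions. Overlaps of 10 nt between opposite strands, which ping-pong amplification of piRNAs gives, were 6.45% of all overlaps with z = 3.76.

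The elements differed in strand, while their 10 nt shares were not tested against each other. The 3 pol regions (gypsy and 1 further element each of the follicle-cell and intermediate lists) are named with less certainty than copia and jockey, and so is their place in these lists. Of the germ-line list, copia (a retrotransposon with long terminal repeats) had 1920 RPM over all 1373 codons, 69.1% antisense (95% CI 68.4 to 69.7%), with a 10 nt share of 6.99% and z = 5.95. The non-LTR retrotransposon jockey had 2092 RPM over its second reading frame, 56.6% antisense (95% CI 55.9 to 57.3%), with a 10 nt share of 7.53% and z = 5.15. Of the follicle-cell list, the pol region of gypsy had 702 RPM and was 80.4% antisense (95% CI 79.4 to 81.3%). Its 10 nt share was 4.63% with z = 0.261. Its overlaps rose from 2.51% at 1 nt to 6.18% at 23 nt, which widens the SD behind this z. The further gypsy-group element of that list was 77.8% antisense (95% CI 76.7 to 78.9%), with a share of 5.94% and z = 1.94. The element of the intermediate list had 1929 RPM and was 92.3% antisense (95% CI 91.9 to 92.7%), with 82.4% 1U in antisense reads and z = 1.38. In each of the 3 pol regions, pairs of 10 nt outnumbered those of 9 and of 11 nt. They were 466 against 357 and 402 for gypsy, and 447 against 376 and 375 for the further gypsy-group element. For the element of the intermediate list they were 748 against 611 and 540. Sense reads had 10A above the share of A at other positions in copia (49.9% against 39.2%), jockey (44.1% against 33.0%), gypsy (36.3% against 29.2%), the further gypsy-group element (56.5% against 34.6%) and the element of the intermediate list (49.9% against 33.7%). In reads of 21 nt, the siRNA length, the strands were nearer to even, with 375 sense and 462 antisense reads over the 5 elements.

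**Figure D2:**
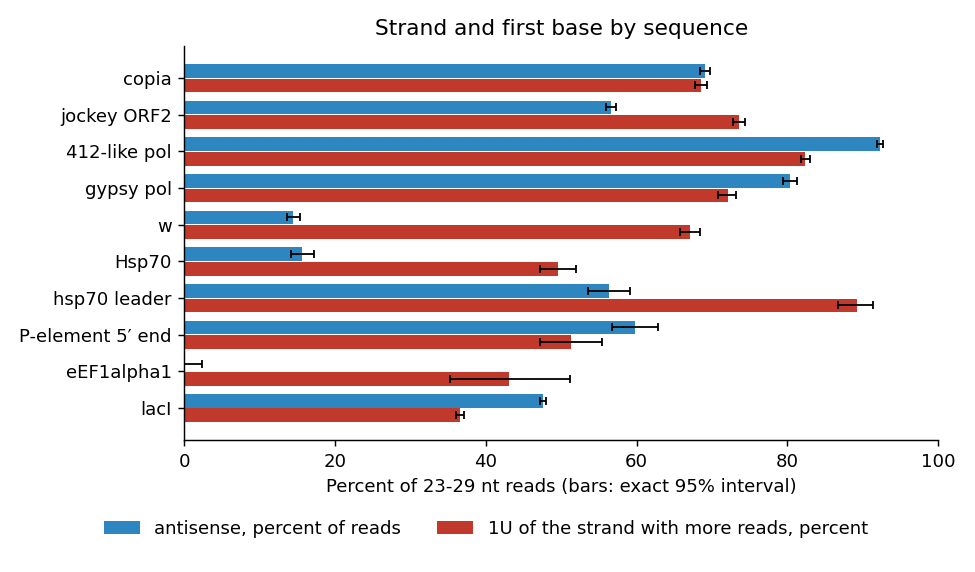
Percent of 23 to 29 nt reads that were antisense (blue) and percent with 1U on the strand with more reads (red) for 4 transposons, the genes w and Hsp70, the hsp70 leader, the P-element 5′ end, the mRNA of eEF1alpha1 and the bacterial gene lacI; lines are exact 95% intervals of 1 library. Transposons were 56.6 to 92.3% antisense, w was 14.4% antisense with 67.1% 1U, and lacI was 47.5% antisense with 36.6% 1U.

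Of the sequences that P-element transgenes commonly carry, w, Hsp70, the hsp70 leader and the P-element 5′ end gave small RNAs of both strands, while y and lacZ had few reads (6 and 56). The white gene (w, FBgn0003996), whose eye-colour product marks many fly transgenes, had 6085 reads of 23 to 29 nt over its coding sequence, or 626 RPM (95% CI 611 to 642). These covered all 687 codons, against 11 reads for the protein written backwards. Of the w reads, 14.4% were antisense (95% CI 13.6 to 15.3%), and 22.5% when each distinct sequence was counted once and 9.94% without sequences read once. Sense w reads began with U in 67.1% (95% CI 65.8 to 68.4%) and antisense w reads in 61.7% (95% CI 58.4 to 65.0%), against 19.8% and 19.7% U at positions 2 to 9. The 10 nt share of w was 4.57% with z = 0.342. Both strands were present in each of 35 bins of 60 nt along the coding sequence, and antisense reads outnumbered sense reads in none, with 83 reads of each strand in the bin at the start codon. In reads of 21 nt there were 90 sense and 52 antisense w reads. Whether they came from the transgene or from the gene on the X chromosome was not analysed here.

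**Figure D3:**
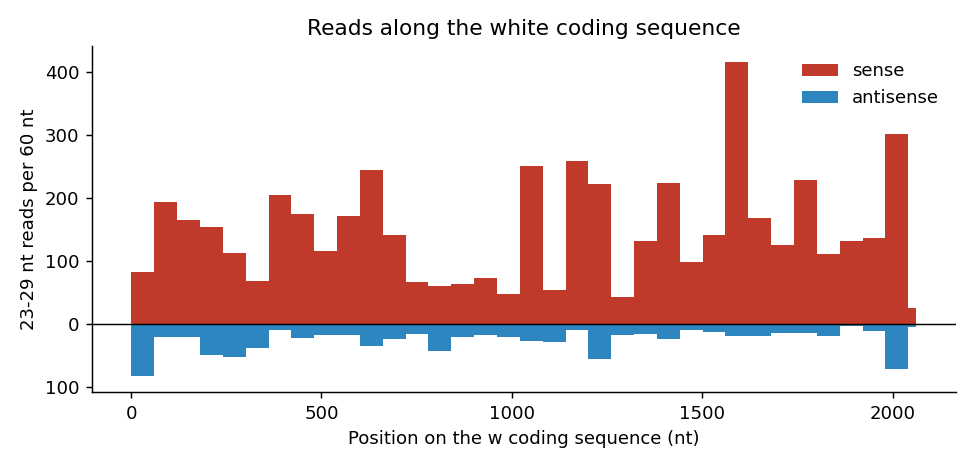
Number of 23 to 29 nt reads per 60 nt along the w coding sequence (nt), sense above and antisense below the line, in 1 library. Sense reads reach 416 in a bin with a median of 137, and antisense reads reach 83 with a median of 19.

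Heat-shock sequences were read as well. Reads of the Hsp70 coding sequence may come from any of 6 nearly identical gene copies, or from related genes that encode the same residues. The Hsp70 coding sequence had 221 RPM (95% CI 212 to 231), and 352 RPM when each distinct sequence was counted once. It was 15.6% antisense (95% CI 14.1 to 17.2%), with 1U in 49.6% of sense and 69.9% of antisense reads, and its 10 nt share was 6.76% with z = 3.0. The hsp70 leader, a 243 nt untranslated stretch used with the hsp70 promoter in many fly vectors, had 129 RPM (95% CI 122 to 136) and was 56.3% antisense (95% CI 53.5 to 59.1%). Its antisense reads began with U in 89.2% (95% CI 86.7 to 91.4%) and its sense reads in 23.8% (95% CI 20.3 to 27.6%). Its sense reads had 10A in 67.2% against 45.3% A at other positions, and 14.6% of its overlaps were 10 nt with z = 4.50. Overlaps of 13 nt were 12.5%. The leader reads were of 221 distinct sequences only. Whether they came from a transgene or from the Hsp70 gene copies was not analysed here.

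The P-element 5′ end, 246 nt that every P-element vector carries, had 102 RPM (95% CI 95.5 to 108). Reads covered 96.7% of it, with 397 sense and 591 antisense reads. Its sense reads began with U in 80.4% (95% CI 76.1 to 84.1%) and its antisense reads in 51.3% (95% CI 47.2 to 55.4%). Its antisense reads had 10A in 43.3%, for which the share of A at other positions was not computed. The 10 nt share was 6.86% with z = 1.75, below the 9.14% of overlaps of 6 nt. The coding sequence of P transposase had 11.6 RPM over 17.4% of its codons, with 110 of 113 reads antisense. Whether these reads lie in a part that vectors keep was not analysed here. The yellow gene (y), another common marker, had 6 reads against 10 for its backwards protein. Act5C (cytoplasmic actin) had 28.1 RPM, with all 44 antisense reads near its 3′ end, and Adh (alcohol dehydrogenase) 1.75.

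Read density on w was above that on 4 other fly mRNAs, whose amounts in these ovaries were not measured. Per kb of coding sequence w had 304 RPM (95% CI 296 to 312), Hsp70 115, Act5C 24.9, eEF1alpha1 (a translation elongation factor) 11.7, alphaTub84B (tubulin) 5.57 and Adh 2.28. The reads of eEF1alpha1 and alphaTub84B were all sense, 158 and 73 reads. Bacterial genes of cloning vectors were also read, as given in the closing section, and lacI reads began with U in 36.6% of sense and 32.2% of antisense reads.

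**Figure D4:**
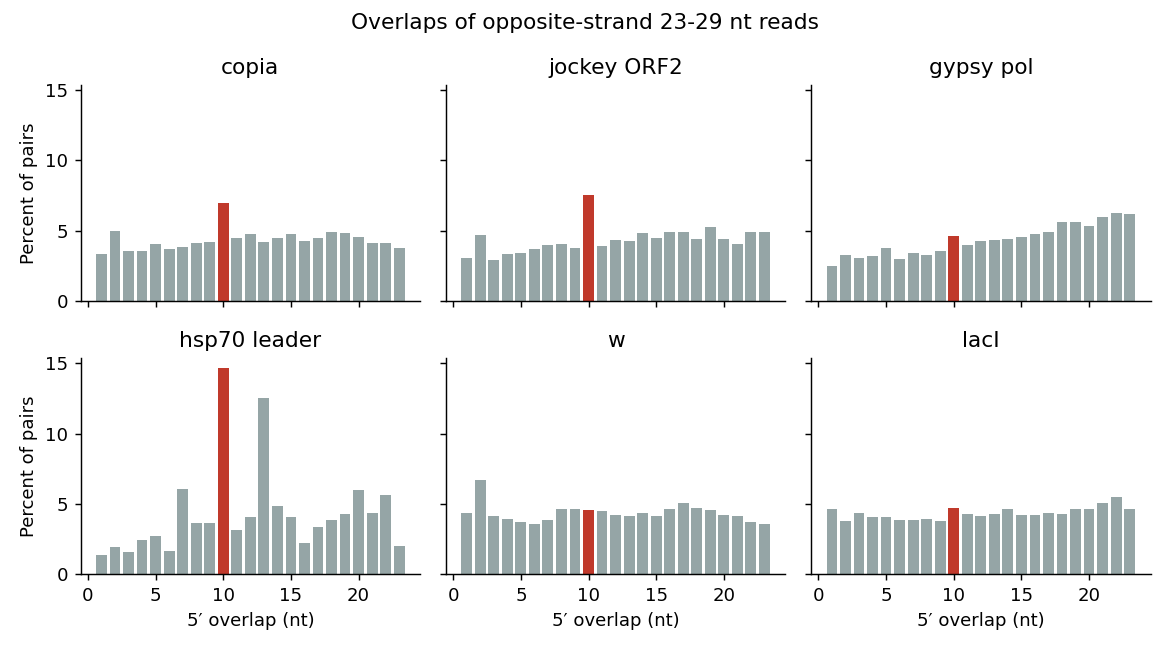
Percent of pairs by overlap (nt) of the 5′ ends of opposite-strand 23 to 29 nt reads, for 3 transposons, the hsp70 leader, w and lacI in 1 library; the red bar is 10 nt. The bar at 10 nt is over 1.5 times both neighbours for copia (6.99%), jockey (7.53%) and the hsp70 leader (14.6%), slightly above them for gypsy (4.63%) and lacI (4.74%), and level with them for w (4.57%).

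Of the protein-coding gene list, vas, which encodes the germ-line RNA helicase Vasa, was the member analysed here. Its coding sequence had 236 RPM (95% CI 226 to 246), and 89.0% of them were antisense (95% CI 87.6 to 90.2%). Reads covered 71.1% of its codons, and the protein written backwards matched 22 reads. The antisense reads began with U in 87.3% (95% CI 85.8 to 88.8%). The 10 most read sequences held 52.6% of vas reads, against 9.58% for w, and the 10 nt share was 2.92% with z = -0.501.

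Unitigs built from the reads gave the overlap over the library without names. The 7235 unitigs added up to 418 kb, with a median of 50 nt and a longest of 372 nt, and 23.2% of 23 to 29 nt reads matched them. Overlaps of 10 nt were 7.31% of all (z = 3.01), with 122227 pairs against 61306 at 9 nt and 73190 at 11 nt, and 4.80% when each distinct sequence was counted once. Outside vector sequences, 3887 unitigs had at least 100 reads. Of these, 34.0% had at least 90% of reads on 1 strand, and 3141 had 1U in at least 50% of reads.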

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

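The reads listed in this part lie outside the main measurement, and all tests in it were chosen after the results had been seen. The strain design gives no group that could set a biological explanation apart, so none was tested by comparison. Reads that hold the 8-base PmeI site numbered 972746, or 6.99% of the library, where the median of 1119 other orders of the same bases was 2613 reads and the highest 365991. Their commonest lengths were 26 and 21 nt. Reads that still held adapter numbered 1232709 (8.86%), of which 811030 had an insert of at least 18 nt.

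Reads of 22 nt were only 5.63% of the mean of 21 and 23 nt. Among reads that still hold adapter, inserts of 22 nt were 98.8% of the mean of 21 and 23 nt. This goes against a scarcity of 22 nt RNA in the sample only if adapter stayed on at similar rates at these lengths. Inserts with adapter numbered 18635 beside 1065177 deposited reads of 21 nt, 54061 beside 77034 of 22 nt, and 90807 beside 1671569 of 23 nt. The ratios were thus unlike, above all at 22 nt. The 98.8% is therefore a rough value that cannot decide whether 22 nt RNA was scarce, though the 54061 inserts lay between those of 21 and 23 nt. Why 22 nt reads are scarce in the deposited list stays open.

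Coding sequences of cloning-vector genes held 63401 reads of 23 to 29 nt for lacI (the lac repressor), 42141 for tetA (a tetracycline pump) and 17319 for bla (beta-lactamase), against 56 for lacZ and 7 for neo. If lacI and tetA had been read into piRNAs, most of their reads should begin with U, but only 33.7% did (95% CI 33.4 to 34.0%), against 19.5% U at positions 2 to 9 of these reads and 70.1% 1U in transposon reads. For bla the share was 55.2%, with 10 nt overlaps at z = 0.0369, so a piRNA origin of bla reads can neither be excluded nor held. Vector nucleic acid from outside the flies is a candidate source of lacI and tetA reads that was not tested by a blank library. Without adapter, PmeI-site and vector coding reads together, the 1U share of 23 to 29 nt reads was 67.1%, and the part of each was not measured.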

How the results depend on the processing

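No paired analysis was possible because there is 1 library. Over 9 results, 31 alternative values were computed and 4 stayed inside the counting interval of the result. Intervals are narrow at this depth, and 4 of these values differed from the result by over 1.5 times. Of the 31, 11 were added after the data had been seen, among them all for unitigs and for the strand of w reads. The cause was not tested. With each distinct sequence counted once, reads of 23 to 29 nt were 70.3%, 1U 59.7%, transposon reads antisense 65.7%, the 10 nt share 5.20% for transposons and 4.80% for unitigs, w 727 and Hsp70 352 RPM, w reads antisense 22.5%, and 20 to 22 nt reads of miRNAs 0.0802%. Without sequences read once these were 70.1%, 64.7%, 76.0%, 8.83%, 9.16%, 642 (inside its interval), 176, 9.94% and 27.2%. At 24 to 28 nt, 1U was 61.9%, transposon reads antisense 74.1% and the unitig share 7.16%. Without listed miRNAs and rRNA, 70.2% were of 23 to 29 nt and 60.8% had 1U. With 1 mismatch, miRNAs held 25.5%. Of the others added, leaving out adapter, PmeI-site and vector coding reads gave 77.3% and 67.1%, adding clipped inserts gave 76.6% of 23 to 29 nt, and leaving out vector unitigs gave a share of 7.73%. Transposon reads stayed mainly antisense, w reads mainly sense, and 1U at 59.7% or more under these alternatives. Of 46 alternatives fixed before the data were examined, 18 were run (20 values, as w and Hsp70 count apart). The other 28 were not run, 22 for results that need a genome and 6 that allow mismatches or weigh multiple genomic matches.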

Other observations

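Tests in this part were chosen after the results had been seen, except for the miRNA share with 1 mismatch. Antisense reads of Act5C, 44 in all, lay in the last 20% of its coding sequence, from nt 971 of 1128, where 169 of its 229 sense reads lay as well. Antisense reads were absent from eEF1alpha1 and alphaTub84B, which allows up to 4.93% antisense for alphaTub84B. Overlaps of 2 nt made up 6.73% of pairs for w, 4.97% for copia and 4.68% for jockey, against 3.75% for lacI and 3.29% for gypsy.

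Mismatches to the listed miRNAs gathered at 2 positions of the read. Over 26 miRNAs with at least 5000 reads, the median mismatch share was 1.45% at position 3, 2.17% at position 4 and 0.467% over the other positions of the first 20. mir-305 had 15.1% at position 4 and bantam 4.79%. The commonest sequence with the PmeI site had 3.50% at position 3, 5.01% at position 4 and 0.564% elsewhere. With 1 mismatch allowed, listed miRNAs held 25.5% of 20 to 22 nt reads instead of 21.7%.

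The small RNAs of w came from both strands along the whole coding sequence, and ping-pong pairs within w are argued against by a 10 nt share of 4.57% with z = 0.342. Unspecific fragments of w mRNA stay open. With all reads counted, 14.4% of w reads were antisense (95% CI 13.6 to 15.3%), above 4 mRNAs pooled (8.64%, 95% CI 6.37 to 11.4%). The w share was not separated from the 16.1% of Act5C (95% CI 12 to 21%). Act5C gave 44 of the 45 antisense reads of the pool, all in the last 20% of its coding sequence. Act5C and Adh are themselves on the list of transgene parts, so they are no clean control for w. The mRNAs outside that list, eEF1alpha1 and alphaTub84B, had no antisense reads (upper bounds 2.31% and 4.93%). Without sequences read once the w share was 9.94%, but the pooled share was not recomputed in that way. Against such fragments goes 1U in 66.3% of w reads (95% CI 65.1 to 67.5%). In the pooled mRNA reads it was 47.0% (95% CI 42.7 to 51.4%), but alphaTub84B alone had 54.8% (95% CI 42.7 to 66.5%). The density of w, 12.2 times that of Act5C, rests on mRNA amounts that were not measured. Contaminating vector nucleic acid stays open too. Antisense w reads had 1U in 61.7% (95% CI 58.4 to 65.0%), above lacI and tetA (33.7%) and above antisense bla reads (40.6%). Sense bla reads reached 61.5% (95% CI 60.6 to 62.4%). The origin of bla reads is itself open, so they cannot show what contaminating reads look like. No group without the transgene was analysed, so an origin of w reads in the transgene was not tested.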
